A study of Solanum lycopersicum with 6 samples.

How the data were processed

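The series holds 6 RNA-seq libraries of tomato fruit, 3 of WT (Ailsa Craig) and 3 of an slmyc2 mutant, at 25 days after anthesis. Per the labels' protocols, total RNA was extracted with TRIzol from 3 biological replicates. The groups and replicate numbers were taken from the genotype labels and the titles. The series title names sllbd40 and different stages, and no sample label does.

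Per the submitters' processing notes, the tools TopHat2, HISAT2, StringTie and Cufflinks were named, with no version, role or order. The genome build, annotation release and quantification settings are not given in the sources used here, so no coordinates are printed. The deposited table gives 1 expression signal per gene and library, made by the authors, in a unit that the file header does not name. The values have 2 decimals and sum to nearly the same total in each library (908014 to 936194). TPM are scaled to a common total and FPKM are not, so these totals are nearer to what TPM give. As no unit is named, FPKM could not be excluded. The deposited group means equalled the means of the 3 library columns within 3.33e-07 and were not used. All per-sample columns were matched to a sample by title.

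Sequencing depth is unknown, because no counts were used. The low values of genes found in few libraries gave a faint common step in WT 2 and WT 3. Relative to WT 1, the value of a single read was 0.917 and 1.10 there, resting on 34 and 15 genes. The next best step had 12 and 5 genes. In slmyc2 1 to slmyc2 3 the best step (12, 13 and 17 genes) hardly exceeded the next (10, 10 and 14), so no read value was taken there. Absolute depth, and so the counting error of low genes, could not be had. A gene listed at 0 may be a failed estimate and is given by its value per library.

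Gene identifiers and descriptions were used as the table gives them. The table gives no gene symbols, and 3801 genes are described as unknown protein. The RefSeq gene table of assembly SLM_r2.1 holds no identifiers of this kind and was used only for the synonyms of MYC2. Of 61 locus identifiers fixed in the gene lists, 55 were found and 53 kept, 2 being dropped because the table describes another family, and 6 were not analysed here. Where a symbol comes from the lists and not from the table, the text says so. Near-identical copies can share reads, and members of multigene families are uncertain in that respect.

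The main choices were fixed in advance. The comparison was slmyc2 against WT with limma 3.58.1 in R 4.3.3 (moderated statistics with trend and robust settings) on log2(value + 1), over genes with a value of at least 1 in at least 3 of the 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 and, for a second count, an absolute log2 fold change of at least 1. The design had assumed a named unit such as FPKM, and the same test was used for the unnamed one. The count tests planned in case of counts were not run. The targeted gene had a two-sided exact permutation test. The 23 gene lists, each a pattern over descriptions plus locus identifiers, were jasmonate signalling, jasmonate biosynthesis, wound and jasmonate defence, pathogenesis related, steroidal glycoalkaloid, ripening, ethylene, carotenoid, photosynthesis, cell wall, sugar and starch, phenylpropanoid, ascorbate, auxin, gibberellin, abscisic acid, cell cycle and histones, LOB domain, heat shock, seed, cuticle, lignin and vascular, and ribosomal proteins. They were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over the lists. Principal components used the 500 most variable genes. Named genes were to be the targeted gene, 8 rising and 8 falling genes with the largest log2 fold change among those past the threshold (mean of at least 5 in the higher group, groups not overlapping, annotated), and the 3 members of each list with the smallest p. The middle part of this rule named 0 genes with all 6 libraries.

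Added after the data were examined were the 10 annotated genes with the smallest p, the same rule without WT replicate 3, limma array weights, a covariate from 11 abundant seed storage genes, a comparison without WT 3 and slmyc2 2, and the list tests with an estimated correlation and each library left out in turn. Alternatives chosen before the data were examined were median-of-ratios, quantile and upper-quartile scaling, no filter and a filter at 5, pseudocounts of 0.1 and 5, limma without trend and robust settings, the replicate number as a block, each library left out in turn, and list membership by locus identifier or pattern alone.

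The gene test was tested on simulated data for slmyc2 against WT, drawn for 16549 genes from their means and spreads with 200 genes changed, in 10 runs. With the spread of all 6 libraries it recovered 16.0% of genes changed 2-fold and 62.2% of genes changed 4-fold, and with the spread without WT replicate 3 it recovered 37.7% and 78.8%. Falsely called genes averaged 4.1 and 6.1 per run. Both settings simulated 3 libraries per group, so the smaller comparison without WT replicate 3 was not itself simulated. A simulated list of 101 genes shifted by 0.5 on the log2 scale was called in 10 of 10 runs, and 0 of 220 unshifted lists were. The simulated genes were independent, which real genes are not.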

Results

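Gene expression was measured by RNA sequencing in tomato fruit (Solanum lycopersicum) of the wild type cultivar Ailsa Craig (WT) and of an slmyc2 mutant in the same series. MYC2 is a basic helix-loop-helix transcription factor at the centre of the jasmonate response, the hormone pathway of wounding and defence. The labels give fruit at 25 days after anthesis, 3 biological replicates of each genotype and total RNA. The series title names another mutant, sllbd40, and several fruit stages, whereas the sample labels and the design text name WT and slmyc2, and the sample labels were followed here. Expression values were listed for 34688 genes per library, with 19759 (WT replicate 3) to 20926 (WT replicate 2) genes above 0. The values of a library summed to between 908014 and 936194, a scaled total that does not show the sequencing depth, so depth is unknown and no counting interval was given. In the text below WT 1 to WT 3 and slmyc2 1 to slmyc2 3 are the replicates as numbered in the titles. Values are given as mean ± SD of the deposited expression values, and log2 fold changes are differences of log2(value + 1), slmyc2 minus WT, which understate the change of low genes.

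The targeted gene was not lower in the mutant libraries. MYC2 (Solyc08g076930.1, described in the table as jasmonic acid 3) was listed at 34.3, 44.1 and 87.5 in WT 1 to WT 3 and at 76.5, 104 and 72.7 in slmyc2 1 to slmyc2 3. The means were 55.3 ± 28.3 (SD, n = 3) in WT and 84.5 ± 17.3 (SD, n = 3) in slmyc2, a log2 difference of 0.70 ± 0.36 (SE). The groups overlapped, with a two-sided exact permutation p of 0.3, where 0.1 is the smallest p that 3 against 3 libraries can give, and limma's adjusted p was 0.631. Without WT replicate 3 the difference was 1.08 (limma, adjusted p = 0.0317, against 0.0317 to 0.967 over all alternatives). The labels do not say what the mutation is, and a small lesion can leave the transcript level as it was, so this level does not check the genotype labels.

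The 6 libraries did not part by genotype on the first principal component. This component of the 500 most variable genes held 50.6% of their variance and set WT 1 and WT 2 (scores of -32.1 and -37.1) against WT 3 (34.3), with slmyc2 1, slmyc2 2 and slmyc2 3 at 9.04, 28.1 and -2.21. The second component held 16.7% and parted the genotypes, with WT 1 to WT 3 at 8.47, 8.90 and 20.6 and slmyc2 1 to slmyc2 3 at -3.84, -4.80 and -29.3. Across genes, WT 3 correlated at a mean r of 0.949 with the slmyc2 libraries and of 0.884 with WT 1 and WT 2, while WT 1 and WT 2 correlated at 0.958 with each other. These are correlations over genes, which are not independent replicates. WT 1 and WT 2 both lay on the same side outside the range of the other 4 libraries at 7354 of the 16549 genes tested (44.4%, where chance gives 13.3%), and the next pair of libraries did so at 3091 genes. Seed storage transcripts followed another division, being low in WT 3 and slmyc2 2, as given with the tissue markers.

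**Figure D1:**
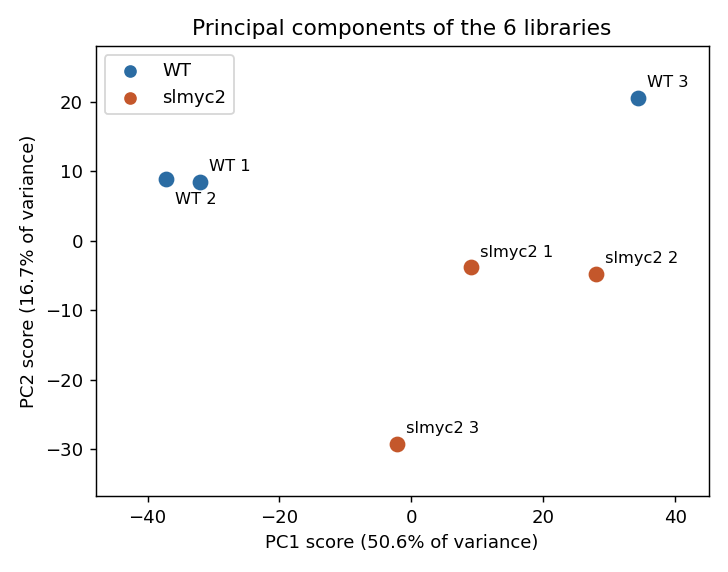
Scores of the 6 libraries on the first 2 principal components of log2(value + 1) over the 500 most variable genes, with WT in blue and slmyc2 in orange; each axis gives its share of the variance. WT 3 (34.3 on the first component) lies beyond slmyc2 2 (28.1), on the other side from WT 1 (-32.1) and WT 2 (-37.1), while on the second component the 3 WT libraries lie above 0 and the 3 slmyc2 libraries below.

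The main question of the design was which genes differ between slmyc2 and WT fruit. The 10 annotated genes with the smallest p were all higher in the 3 mutant libraries than in any WT library, though none passed the test. A pistil-specific extensin-like gene (Solyc02g078040.3), of a family of hydroxyproline-rich cell wall proteins, was listed at 15.9 ± 1.65 (SD, n = 3) in WT and 79.4 ± 15.5 (SD, n = 3) in slmyc2. A gene described as methylecgonone reductase (Solyc03g098100.4) was at 15.6 ± 3.28 and 67.8 ± 23.3, the EID1-like F-box protein 3 (Solyc06g084320.1) at 47.7 ± 8.14 and 156 ± 44.0, and tyrosine/DOPA decarboxylase 3 (Solyc07g054860.1) at 7.85 ± 2.68 and 24.9 ± 2.36. A pleiotropic drug resistance transporter (Solyc06g036234.2) was at 2.92 ± 1.02 and 13.1 ± 2.13, and a RING-type E3 ubiquitin transferase (Solyc03g114160.1) at 0.657 ± 0.306 and 14.0 ± 9.45. A gag/pol polyprotein gene (Solyc11g162260.1), a retrotransposon sequence, was listed at 0 in each WT library and at 31.5, 29.7 and 8.0 in slmyc2. These genes were chosen after their values were seen.

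No gene passed the threshold. Of 16549 genes tested with limma, 0 had an adjusted p under 0.05, and so 0 changed at least 2-fold past it. The smallest adjusted p was 0.191, for the extensin-like gene (log2 fold change 2.23 ± 0.19, SE, higher in 3 of 3 mutant libraries). At an unadjusted p under 0.05 there were 1291 genes (7.8%), of which 782 were higher and 509 lower in slmyc2, a division that quantile normalization turned to 645 higher and 771 lower. Groups did not overlap at 2070 genes (1162 higher, 908 lower), 12.5% of those tested, where chance gives 10%. Grouping WT 1 and WT 2 with slmyc2 1, slmyc2 2 or slmyc2 3 in place of WT 3 gave more such genes (2892, 2170 and 4010). These groupings also gave more genes at limma's unadjusted p under 0.05 (1980, 1443 and 2851). Neither count was therefore particular to the grouping by genotype. Without WT replicate 3 the count of genes past the threshold was 1755 and without slmyc2 replicate 3 it was 1, the gag/pol gene.

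**Figure D2:**
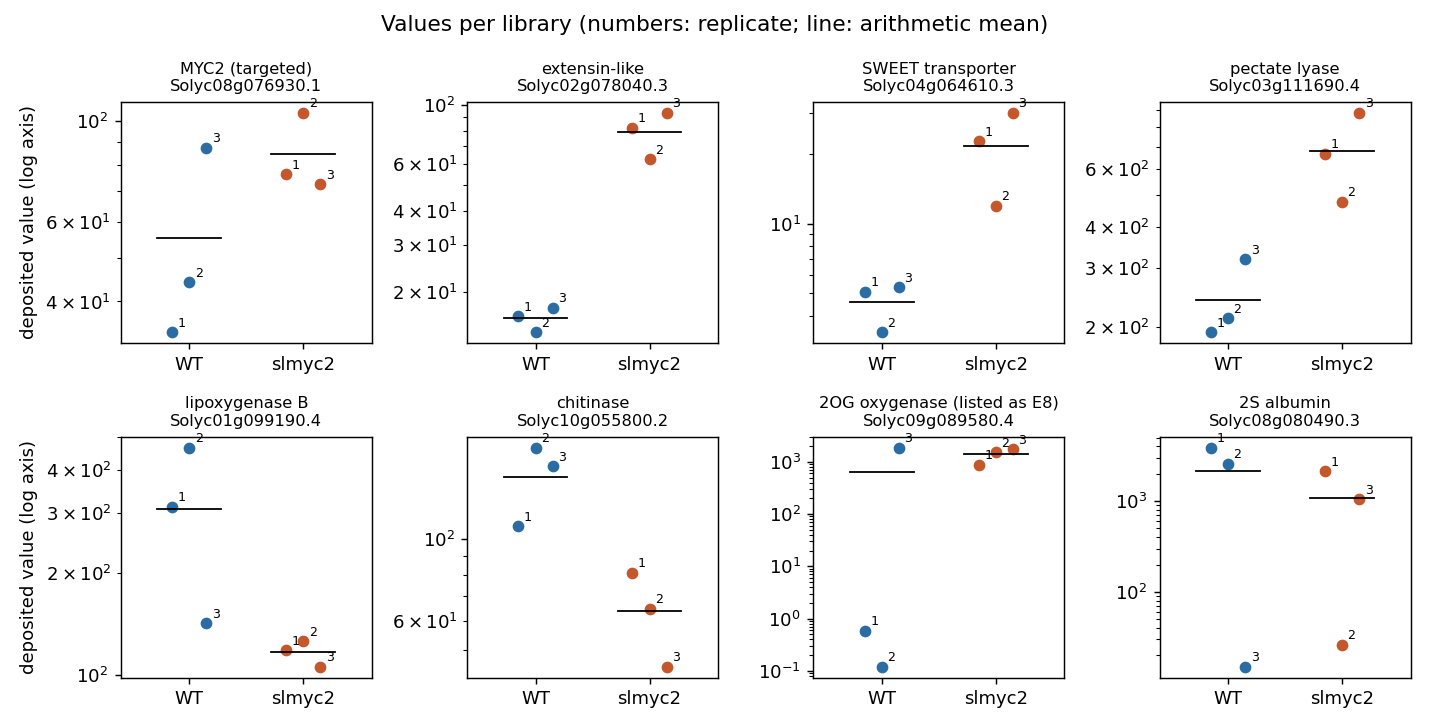
Deposited expression value (log axis, arbitrary scaled unit) of 8 genes in each library, with WT in blue and slmyc2 in orange, the replicate number beside each point and the arithmetic mean as a line. The extensin-like gene is between 14.2 and 17.4 in WT and between 62.8 and 93.4 in slmyc2, whereas the gene listed as E8 is at 0.59 and 0.12 in WT 1 and WT 2 and at 1875 in WT 3.

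The gene lists fixed in advance for the jasmonate pathway and its defence output had 0 members past the threshold. In jasmonate signalling 9 of 13 tested members had a positive and 4 a negative log2 fold change (median 0.22; camera adjusted p = 0.255), and in jasmonate biosynthesis 10 were positive and 12 negative (median -0.04; adjusted p = 0.574). With 1 library left out the signalling median ran from 0.13 (without slmyc2 replicate 3) to 0.38 (without WT replicate 2), but it turned to -0.13 over the 6 genes listed by locus identifier alone and to -0.04 with limma array weights. The biosynthesis median ran from -0.15 (without slmyc2 replicate 3) to 0.12 (without WT replicate 2), the only one of the 6 above 0, and was -0.14 without WT replicate 1. Over the genes listed by locus identifier alone the biosynthesis median was -0.31. Of these, allene oxide cyclase (Solyc02g085730.3; 112, 382 and 56.1 in WT, 51.9 to 64.5 in slmyc2) was highest in WT 2. So were 12-oxophytodienoate reductase 3 (Solyc07g007870.3; 76.1, 180 and 32.8, against 40.5 to 44.7) and the genes listed as AOS1 and LOXD. Those listed as AOS2, LOXC and JAR1 were highest in slmyc2 3. Lipoxygenase B (Solyc01g099190.4), which oxidises linoleic acid, was at 307 ± 162 (SD, n = 3) in WT and 117 ± 10.1 in slmyc2, with WT 3 (142) near the mutant libraries. Ninja-family protein AFP3 (Solyc05g012210.4), of a family of co-repressor adaptors, was at 6.82 ± 4.84 and 20.9 ± 1.49, and a Tify gene (Solyc12g049400.2), of the JAZ repressor family, at 37.8 ± 24.7 and 16.9 ± 4.52. Lipoxygenase B and AFP3 entered these lists through their descriptions and not by locus identifier. Such a match does not show a role in the jasmonate pathway. In the wound and jasmonate responsive defence list 17 of 24 members were negative (median -0.25; adjusted p = 0.106), and without WT replicate 2 the median was 0.003. It was -0.13 without slmyc2 replicate 2, -0.07 without slmyc2 replicate 3 and -0.47 without WT replicate 1, and passed camera only without slmyc2 replicate 1 (median -0.50; adjusted p = 0.0169, and adjusted p = 0.517 with an estimated correlation). The viroid-inducible proteinase inhibitor II (Solyc03g020050.3) was at 6.77 ± 4.78 in WT and 1.32 ± 0.982 in slmyc2. Another proteinase inhibitor (Solyc09g083435.1) was at 36.0 ± 38.1 and 5.39 ± 6.41, its WT mean carried by WT 2 (79.9).

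Pathogenesis related genes stood lower than other genes as a list, with 39 of 57 members negative and 0 past the threshold (median -0.36; camera adjusted p = 0.0411, and adjusted p = 0.474 with an estimated correlation). The call was lost with quantile and upper-quartile scaling (adjusted p = 0.0574 and 0.0609), with a filter at 5 (0.0609), without WT replicate 2 (0.121) and without slmyc2 replicate 2 (0.131). A chitinase (Solyc10g055800.2), an enzyme that cleaves fungal cell walls, was at 147 ± 35.2 (SD, n = 3) in WT and 63.6 ± 18.0 in slmyc2, and pathogenesis-related protein STH-2 (Solyc09g091000.5) at 16.5 ± 2.69 and 8.61 ± 2.33. A thaumatin-like protein (Solyc03g033490.3) went the other way, at 6.10 ± 3.48 and 14.2 ± 0.712. The mean log2(value + 1) of the pathogenesis list was 4.38, 4.82 and 4.20 in WT 1 to WT 3 and 4.24, 4.03 and 4.10 in slmyc2 1 to slmyc2 3, so WT 3 lay among the mutant libraries. Its median was -0.16 without WT replicate 1, -0.12 without WT replicate 2, -0.61 without WT replicate 3 and -0.18 without slmyc2 replicate 3. In the steroidal glycoalkaloid pathway 4 of 5 members were negative (median -0.27; adjusted p = 0.202). With 1 library left out the glycoalkaloid median ran from -0.44 (without slmyc2 replicate 1) to -0.04 (without WT replicate 1 and without slmyc2 replicate 3), and was -0.42 without WT replicate 3. It passed camera only without slmyc2 replicate 1 (adjusted p = 0.0499, and adjusted p = 0.517 with an estimated correlation). A glycosyltransferase of that list (Solyc07g043500.1) was at 6.67 ± 3.0 and 2.89 ± 1.53.

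Ripening, ethylene and auxin lists stood higher in slmyc2, and WT 3 lay apart from WT 1 and WT 2 toward the mutant libraries in each. Of the ripening regulators and markers 20 of 29 were positive (median 0.25; camera adjusted p = 0.0471), of the ethylene genes 62 of 93 (median 0.25; adjusted p = 0.00314) and of the auxin response genes 34 of 52 (median 0.25; adjusted p = 0.0230). With an estimated correlation each of these 3 lists had an adjusted p = 0.474. The mean log2(value + 1) of the ripening list was 5.17 and 5.10 in WT 1 and WT 2, 5.75 in WT 3 and 5.69, 5.88 and 5.92 in slmyc2. Of the ethylene list it was 3.85 and 3.93, then 4.10, and 4.19, 4.48 and 4.21 in slmyc2, and of the auxin list 3.73 and 3.78, then 4.01, and 4.10, 4.17 and 4.08. The ripening call was lost with median-of-ratios and upper-quartile scaling (adjusted p = 0.0556 and 0.0591), under both other filters (0.161 and 0.0513), and without WT replicate 1 (0.0682), WT replicate 2 (0.203) or slmyc2 replicate 3 (0.161). Without a filter the ethylene and auxin calls were lost (0.0732 and 0.0655), and the auxin call without WT replicate 2 (0.0890). The ethylene median turned to -0.33 by locus identifiers alone, which leaves 2 genes. One, 1-aminocyclopropane-1-carboxylate oxidase 1 (Solyc07g049530.3, listed as ACO1), was lower, at 2117 ± 724 (SD, n = 3) in WT and 1141 ± 190 in slmyc2. The other, listed as ACS2 (Solyc01g095080.3), was at 9.64 ± 3.73 and 10.8 ± 2.35. In the ripening list the gene listed as CNR (Solyc02g077920.4) was also lower, at 143 ± 19.2 and 97.4 ± 25.8, with the groups overlapping. No member passed over all genes tested, and adjusted over the list alone 1 ripening gene, 1 ethylene gene and 0 auxin genes did. The ripening gene was a pectate lyase (Solyc03g111690.4), of the enzymes that cleave pectin as fruit softens, at 241 ± 68.4 (SD, n = 3) in WT and 676 ± 204 in slmyc2. The ethylene gene was an ethylene-responsive transcription factor (Solyc07g054220.1) at 3.19 ± 0.0603 and 9.65 ± 0.398. Ripening regulated protein DDTFR10/A (Solyc05g052040.1) was at 34.2 ± 37.8 and 137 ± 89.0, with 77.9 in WT 3 and 13.0 and 11.8 in the other WT libraries. A further ethylene-responsive transcription factor (Solyc12g009240.1) was at 1.64 ± 1.92 and 47.3 ± 52.7, ethylene response factor A.2 (Solyc03g093610.1) at 2.93 ± 1.13 and 11.2 ± 4.60. Among auxin genes, SAUR32 (Solyc06g053260.1) was at 0.967 ± 1.16 and 6.92 ± 1.31, and auxin response factor 8B (Solyc02g037530.3) at 9.58 ± 3.28 and 17.6 ± 3.25. Carotenoid pathway genes were positive in 21 of 31 (median 0.21; adjusted p = 0.0839), a list that passed without WT replicate 3 (median 0.30; adjusted p = 0.0356) and without slmyc2 replicate 1 (median 0.19; adjusted p = 0.0326). With an estimated correlation these had an adjusted p = 0.516 and 0.517, and without slmyc2 replicate 3 the carotenoid median was 0.13 (adjusted p = 0.251). Its library means were 3.74 and 3.79 in WT 1 and WT 2, 3.97 in WT 3 and 3.97, 4.13 and 4.06 in slmyc2, with zeaxanthin epoxidase (Solyc02g090890.4) at 51.0 ± 26.3 and 84.8 ± 8.07.

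Ribosomal protein, photosynthesis and heat shock lists stood lower in slmyc2, by small amounts. Of 192 cytosolic ribosomal protein genes 173 were negative (median -0.18; camera adjusted p = 4.01e-09), of 95 photosynthesis and chloroplast genes 68 (median -0.28; adjusted p = 8.26e-05) and of 205 heat shock genes 128 (median -0.11; adjusted p = 0.0411). With an estimated correlation each of these 3 had an adjusted p = 0.474, and 0 members passed singly. The mean log2(value + 1) of the ribosomal list was 7.56 and 7.55 in WT 1 and WT 2, 7.33 in WT 3 and 7.35, 7.34 and 7.24 in slmyc2, so WT 3 lay with the mutant libraries. That of the photosynthesis list was 4.60, 5.35 and 4.69 in WT and 4.69, 4.59 and 4.46 in slmyc2, its difference carried by WT 2, without which the median was -0.12 (adjusted p = 0.0200). That of the heat shock list was 4.36, 4.48 and 4.28 in WT and 4.26, 4.28 and 4.21 in slmyc2. The heat shock call was lost under both other filters (0.0831 and 0.125), without WT replicate 3 (0.108) and without slmyc2 replicate 2 (0.0674). The 60S ribosomal protein L18a-like gene (Solyc07g041010.3) was at 67.9 ± 8.01 (SD, n = 3) in WT and 46.1 ± 3.58 in slmyc2. Photosystem II protein D1 (Solyc00g277510.2), a reaction centre subunit, was at 6.87 ± 0.880 and 3.98 ± 0.562. Its values were identical at 2 other listed loci, Solyc00g500130.1 and Solyc00g500200.1, so the copies cannot be read as separate genes. A class I heat shock protein (Solyc09g015020.1) was at 10.9 ± 1.92 and 4.01 ± 1.68, and a 70 kDa heat shock protein (Solyc09g075950.1) at 8.74 ± 4.41 and 2.61 ± 0.832. In the whole set 7 of 23 lists passed camera with its preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.474) and 0 with fry (smallest adjusted p = 0.364). The number was 4 without WT replicate 2 and 11 without slmyc2 replicate 1. With each library left out in turn and an estimated correlation, 0 lists passed in any of the 6 comparisons (smallest adjusted p = 0.495).

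**Figure D3:**
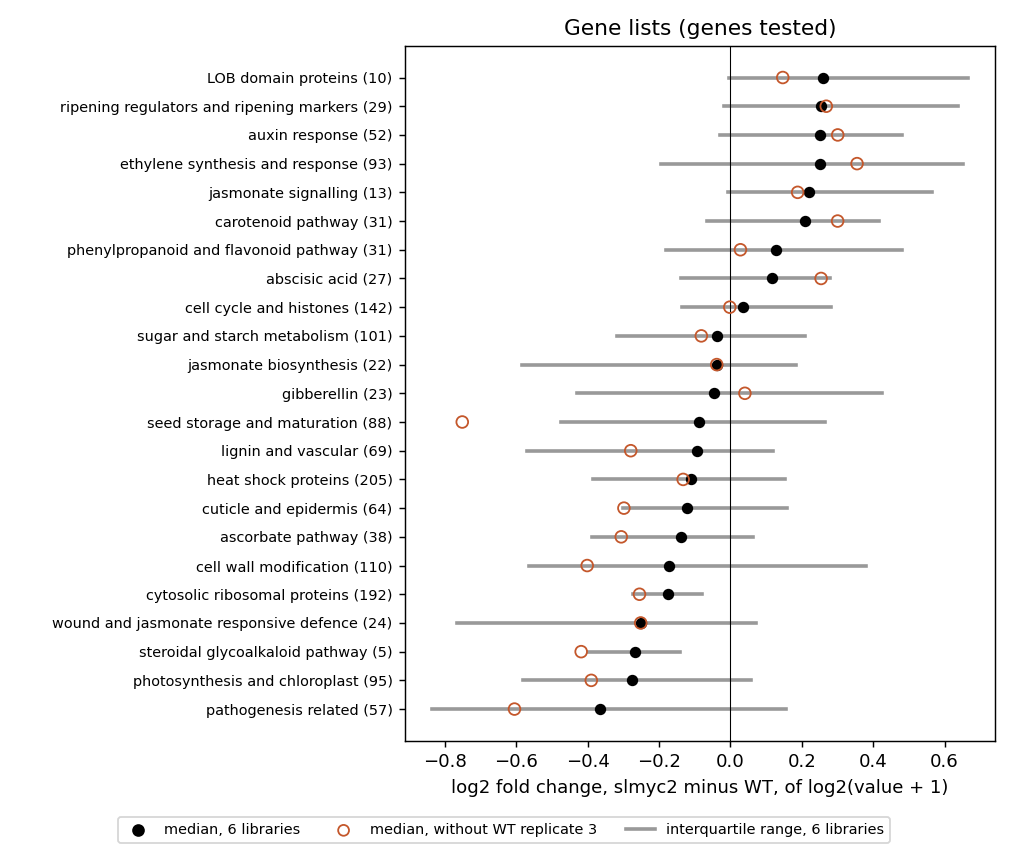
Median log2 fold change (slmyc2 minus WT, of log2(value + 1)) of the tested members of 23 gene lists, with all 6 libraries (black points, grey bars for the interquartile range) and without WT replicate 3 (open circles); the number of tested genes is in parentheses. The seed storage list moves the most between them, from a median of -0.09 to one of -0.75.

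Lists for metabolism and growth did not pass the list test with all 6 libraries, and 0 of their members passed singly. Cell wall modification genes were negative in 67 of 110 (median -0.17; camera adjusted p = 0.202), and passed without WT replicate 3 (median -0.40; adjusted p = 0.0231, and adjusted p = 0.516 with an estimated correlation). Without WT replicate 1 and without WT replicate 2 the median was -0.05. Their mean log2(value + 1) was 3.84, 3.86 and 3.17 in WT and 3.52, 3.66 and 3.52 in slmyc2. Pectin methylesterase 1 (Solyc07g064170.3) was at 1599 ± 482 (SD, n = 3) in WT and 859 ± 79.1 in slmyc2, and a pectinesterase inhibitor-like gene (Solyc01g160470.1) at 4.50 ± 1.95 and 0.933 ± 0.182. Sugar and starch genes were divided, 49 positive and 52 negative (median -0.04; adjusted p = 0.673), with a median of -0.08 (without WT replicate 3) to 0.02 (without WT replicate 2) with 1 library left out, 0.007 under both other filters and 0.16 over the 5 genes listed by locus identifier alone. A SWEET sugar transporter (Solyc04g064610.3) was at 4.60 ± 1.05 and 21.6 ± 9.16, another (Solyc05g024260.3) at 64.3 ± 7.75 and 164 ± 77.5, and an ATP-dependent 6-phosphofructokinase (Solyc04g015200.3), an enzyme of glycolysis, at 29.8 ± 6.63 and 72.7 ± 24.0. Phenylpropanoid and flavonoid genes were positive in 20 of 31 (median 0.13; adjusted p = 0.202), with a median of 0.03 without WT replicate 3 and 0.20 without slmyc2 replicate 3. Among them was phenylalanine ammonia-lyase (Solyc10g086180.2), the entry enzyme of the pathway, at 25.1 ± 22.1 and 113 ± 48.0. Ascorbate genes were negative in 23 of 38 (median -0.14; adjusted p = 0.107), and passed without WT replicate 3 (median -0.31; adjusted p = 0.0352) and without slmyc2 replicate 1 (median -0.23; adjusted p = 0.0499). With an estimated correlation these had an adjusted p = 0.516 and 0.630, and without WT replicate 2 the ascorbate median was -0.03. Their library means were 4.54, 4.69 and 4.06 in WT and 4.26, 4.31 and 4.15 in slmyc2, with cytosolic ascorbate peroxidase 1 (Solyc06g005160.4) at 188 ± 50.2 and 113 ± 16.1. Medians were -0.05 for gibberellin (23 genes; adjusted p = 0.735), where the mean was 0.002, 0.12 for abscisic acid (27 genes; adjusted p = 0.402), 0.04 for cell cycle and histones (142 genes; adjusted p = 0.402) and 0.26 for LOB domain proteins (10 genes; adjusted p = 0.368). With 1 library left out these 4 medians ran from -0.07 to 0.09, 0.08 to 0.25, -0.002 to 0.09 and 0.15 to 0.41, and none of the 4 lists passed. The gibberellin median turned to 0.26 with a filter at 5 (14 genes), where the LOB domain median was 0.57 (6 genes), and the cell cycle median to -0.02 without both WT 3 and slmyc2 2. The stress-inducible TAS14 gene (Solyc02g062390.3) of the abscisic acid list was at 49.2 ± 5.74 and 125 ± 46.4.

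Seed storage markers differed between libraries of the same genotype. Of the seed storage and maturation list 53 of 88 were negative (median -0.09; camera adjusted p = 0.662). The median turned with the library left out, being 0.20 without WT replicate 1, 0.41 without WT replicate 2, -0.75 without WT replicate 3, -0.09 without slmyc2 replicate 1, 0.33 without slmyc2 replicate 2 and -0.49 without slmyc2 replicate 3. The list passed without WT replicate 3 (adjusted p = 0.0116) and without slmyc2 replicate 3 (adjusted p = 0.0386), and with an estimated correlation these had an adjusted p = 0.516 and 0.702. Adjusted over the list alone 1 gene passed, a lipid-transfer superfamily gene (Solyc08g078870.3) at 94.4 ± 11.1 (SD, n = 3) in WT and 185 ± 11.8 in slmyc2. Storage protein genes were abundant in 4 libraries and near absent in WT 3 and slmyc2 2. The 2S albumin gene (Solyc08g080490.3) was listed at 3894, 2593 and 15.02 in WT and at 2140, 26.2 and 1051 in slmyc2. The 11S globulin gene (Solyc09g072560.5) was at 1908, 1774 and 9.46 and at 989, 17.0 and 420. Cuticle and epidermis genes were negative in 41 of 64 (median -0.12; adjusted p = 0.255), and passed without slmyc2 replicate 3 (median -0.17; adjusted p = 0.0163, and adjusted p = 0.702 with an estimated correlation). Their median was -0.05 without WT replicate 1 and without WT replicate 2, -0.30 without WT replicate 3, -0.19 without slmyc2 replicate 1 and 0.05 without slmyc2 replicate 2. They too were low in WT 3 and slmyc2 2, with a mean log2(value + 1) of 3.53 and 3.52 there, against 4.33 and 4.15 in WT 1 and WT 2 and 4.07 and 4.23 in slmyc2 1 and slmyc2 3. Of the 64 genes 22 (34.4%) were lower in both than in the other 4 libraries, as were 44 of the 88 genes of the seed list and 7.40% of all tested genes. Among the cuticle and epidermis genes was a non-specific lipid-transfer protein (Solyc10g075090.3) at 4178 ± 866 and 7302 ± 1548. Lignin and vascular genes were negative in 39 of 69 (median -0.09; adjusted p = 0.202), with a median of -0.28 without WT replicate 3 and -0.05 without WT replicate 1 and without WT replicate 2. Among them was a peroxidase (Solyc03g025380.3) at 32.8 ± 17.4 and 6.35 ± 3.68. Adjusted over the list alone, 0 genes passed in any of the other 20 lists.

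Left without WT replicate 3, the comparison of WT 1 and WT 2 with the 3 slmyc2 libraries gave 1755 genes past the limma threshold, 901 higher and 854 lower, of which 1203 changed at least 2-fold. The genes named here follow the rule fixed in advance, applied after the values were seen to this smaller comparison. Among the risen genes that the rule named, the largest log2 fold change (9.96 ± 0.33, SE) was that of a 2-oxoglutarate-dependent oxygenase (Solyc09g089580.4). This gene, listed in advance as E8 and known for its ripening expression, was at 0.59 and 0.12 in WT 1 and WT 2 and at 878 to 1743 in slmyc2. Others that rose were a gene described as maternal effect embryo arrest 59 (Solyc06g006000.3, 7.22 and 5.56 against 166 to 233), glycolate oxidase (Solyc10g007600.3, a photorespiration enzyme, 62.0 and 251 against 1838 to 2745) and a light-regulated protein (Solyc09g092110.5, 3.11 and 8.78 against 83.0 to 161). An endo-1,4-beta-xylanase (Solyc01g111340.4) and histidine decarboxylase (Solyc08g066240.3) rose by 4.59 ± 0.40 and 4.05 ± 0.37 (SE) on the log2 scale, and the ethylene-responsive transcription factor Solyc12g009240.1 by 4.42 ± 0.86 (SE). The gag/pol gene (Solyc11g162260.1), listed at 0 in both WT libraries, also rose. Among the genes that fell were a subtilisin (Solyc08g079870.3, 74.7 and 63.4 against 2.01 to 4.55), a wound induced protein (Solyc07g054780.1, 387 and 344 against 14.8 to 37.4), a class II chitinase (Solyc02g082920.5, 387 and 450 against 31.1 to 64.7) and a polygalacturonase inhibiting protein (Solyc09g014480.3, 31.2 and 114 against 3.05 to 5.39). A hypoxia-responsive gene (Solyc06g050870.3), a calcium-dependent lipid-binding gene (Solyc02g063355.1) and a dirigent protein gene (Solyc02g082740.1) had log2 fold changes of -4.59, -3.81 and -3.22. A pectate lyase (Solyc02g031960.3), other than the one of the ripening list, was at 32.9 and 8.69 in WT 1 and WT 2, against 0.63, 1.73 and 0 in slmyc2 1 to slmyc2 3 (log2 fold change -3.46, limma's adjusted p = 0.0335, against 0.0335 to 0.967 over all alternatives). WT 3 itself was nearer to the slmyc2 mean than to that of WT 1 and WT 2 at 1637 of the 1755 genes (93.3%), among them the E8 gene at 1875 and the subtilisin at 4.14. With this library in the comparison, 0 of these genes passed.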

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

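The count of 0 genes past the threshold held under the 3 scalings, both filters, both pseudocounts, limma without trend and robust settings and the covariate for seed storage genes. It did not hold when WT replicate 3 was left out or weighted down. Leaving out each library in turn gave 0 to 1755 genes, and 0 to 1203 changed at least 2-fold, the highest without WT replicate 3. Without slmyc2 replicate 3 there was 1, and without each of the others 0. Among alternatives chosen after seeing the data, limma array weights gave 1276 genes (833 at least 2-fold), with a weight of 0.232 for WT 3, and leaving out both WT 3 and slmyc2 2 gave 740 (729 at least 2-fold). In each of these the library that stood apart in its group carried less weight or none. The log2 fold change of MYC2 was 0.42 to 1.08 with a library left out and stayed positive throughout, passing the threshold only at 1.08, without WT replicate 3. The 7 gene lists past the camera threshold were 3 without a filter, 4 with a filter at 5 and 0 with an estimated correlation. With a library left out their number was 4 (without WT replicate 2) to 11 (without slmyc2 replicate 1), and the cause was not tested. Only 8 lists could be tested by locus identifiers alone, and 0 of them passed. Of the 7, the ripening and ethylene lists alone were among these 8. By locus identifiers alone the median of the ethylene list turned from 0.25 to -0.33 (2 genes), that of jasmonate signalling from 0.22 to -0.13 (6 genes) and that of sugar and starch from -0.04 to 0.16 (5 genes). A further 3 medians moved by over 1.5 times with the same sign. These were jasmonate biosynthesis (-0.04 to -0.31), wound and jasmonate responsive defence (-0.25 to -0.65) and carotenoid (0.21 to 0.05). The tested wound genes listed by locus identifier were all highest in WT 2. That listed as TD2, for example, was at 1.82, 55.7 and 2.69 in WT and 12.8, 3.18 and 3.41 in slmyc2. The 3 scalings, both pseudocounts and the replicate block turned no list median, whereas it turned for sugar and starch (0.007 each) and gibberellin (0.02 and 0.26) without a filter and with a filter at 5. Array weights turned jasmonate signalling (-0.04) and cell cycle and histones (-0.009), the seed covariate turned the seed list (0.001), and leaving out both WT 3 and slmyc2 2 turned gibberellin (0.02) and cell cycle and histones (-0.02). With 1 library left out, 1 to 4 list medians turned. Without a filter 15 further medians moved by over 1.5 times with the same sign, and with a pseudocount of 5 it was 9. The excess of the correlation of WT 3 with slmyc2 over that with WT 1 and WT 2 was 0.0656 and fell to 0.0347 without a filter, still in the same direction; the cause was not tested. None of the genes named by the rule or for their small p changed direction under any alternative in which it was tested. Apart from MYC2 these genes were chosen for a small p or for groups that did not overlap. A change of direction was therefore unlikely from the start, and its absence says little. With the replicate number as a replicate block, 0 genes and 7 lists passed and the log2 fold change of MYC2 was 0.70, so no call changed. The numbers gave no sign of pairing the libraries: deviations from the group mean correlated across genes at -0.03, -0.18 and -0.25 between libraries of the same number, and WT 3 correlated best with slmyc2 2 (0.26). Deviations from a group mean cancel within each genotype, so these correlations depend on each other and cannot exclude a pairing. Count tests and a second unit were not run, since counts were not used here. Depth limits what can be said of low genes, and is unknown.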

Other observations

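Beyond the lists fixed in advance, some clock and light genes set WT 1 and WT 2 apart from the other 4 libraries. Of 39 clock and CONSTANS family genes 20 did so (51.3%), against 44.4% of the other 16510 genes tested (Fisher's exact p = 0.422), so the family was not shown to do so more often than other genes. GIGANTEA (Solyc04g071990.3), a clock protein, was listed at 27.4 and 39.4 in WT 1 and WT 2, at 74.9 in WT 3 and at 62.0 to 72.1 in slmyc2, whereas a second GIGANTEA gene (Solyc12g056650.2) was at 46.6 and 81.7, with the other 4 libraries between them at 53.3 to 68.6. A CONSTANS-like zinc finger gene (Solyc07g053140.3) was at 10.7 and 11.7, then 84.5, and 76.7 to 85.9 in slmyc2. REVEILLE 1 (Solyc03g098320.5) went the other way, at 10.9 and 8.40, then 1.45, and 1.32 to 3.43. The gene listed in advance as E8 (Solyc09g089580.4) was at 0.59 and 0.12 in WT 1 and WT 2 and at 878 or more in each other library. Of the 29 tested genes of the ripening list 17 (58.6%) set WT 1 and WT 2 apart, against 44.4% of all tested genes, a difference that was not tested. The share was higher in the carotenoid list (61.3%) and the ribosomal protein list (59.4%), and lower in every other list. The 17 ripening genes include the NAC gene listed as NOR (Solyc10g006880.3), at 173 and 159, then 472 in WT 3, and 262 to 354 in slmyc2. Not all genes linked to ripening shared this: phytoene synthase 1 (Solyc03g031860.3) was at 526, 477 and 462 in WT and 318 to 521 in slmyc2, and the peptide methionine sulfoxide reductase listed as E4 (Solyc03g111720.3) at 1062, 1024 and 1678 and 968 to 1451. These genes were chosen after their values were seen.

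The tests of the WT 3 and seed patterns, and of the gene counts over splits of all 6 libraries, were chosen only after the results they measure had been seen, at least in part. The tests over splits for the gene lists and for the genes without WT replicate 3 were chosen before their results were seen.

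WT replicate 3 stood with the slmyc2 libraries rather than with WT 1 and WT 2 on the first principal component and in its correlations, though not on the second component (20.6). At genes where WT 1 and WT 2 lay more than 2-fold apart from a pair of slmyc2 libraries, WT 3 was nearer to WT 1 and WT 2 more often than the slmyc2 library left out of the choice in 2 of the 3 comparisons (14.8% against 12.2% for slmyc2 1, 11.7% against 8.28% for slmyc2 2) and less often in 1 (8.78% against 20.6% for slmyc2 3). The 95% exact intervals overlapped in the 2 comparisons where WT 3 had the larger share, and not in the 1 where it had the smaller. These intervals count genes as independent, which they are not, and both libraries of a comparison were scored on the same genes. Whether they overlap therefore does not decide between the libraries. A mislabelled library so stays open, as does, untested, a WT fruit in the state of the mutant fruit. For less seed tissue in WT 3, 819 genes were more than 2-fold higher there than in WT 1 and WT 2. At 66.3% of them (95% exact interval 62.9 to 69.5, genes again counted as independent) the seed-rich slmyc2 1 and slmyc2 3 were both nearer to WT 3. Both were nearer to WT 1 and WT 2 at 6.84%. This argues against less seed tissue at those 66.3% only if the genotype left them unchanged, which was not tested. For the 1317 genes more than 2-fold lower in WT 3 the share with both nearer to WT 3 was 44.7%, with both nearer to WT 1 and WT 2 at 21.6%. Seed tissue so stays open in both sets. Time of day or light at harvest cannot be told apart from other causes: 51.3% of the clock and CONSTANS family genes set WT 1 and WT 2 apart, against 44.4% of the other genes (Fisher's exact p = 0.422), and the labels give no harvest time.

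Seed storage transcripts were low in WT 3 and slmyc2 2, one library of each genotype. Of 11 abundant seed storage genes 10 were lower in both than in the other 4 libraries, the exception being a caleosin (Solyc01g005410.5), with median log2 differences of -5.92 in WT 3 and -4.69 in slmyc2 2 from the other libraries of their genotype. Library scaling is excluded, since over all genes the medians were -0.07 and 0.10. Less seed in the tissue taken for these libraries is a candidate explanation that goes with these values, but the cuticle and epidermis list was low in both as well (mean log2(value + 1) of 3.53 and 3.52, against 4.07 to 4.33 in the other 4), so the difference was not confined to seed markers. The seed pattern does not set the genotypes apart, and with the seed covariate 0 genes passed between them.

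Among the 10 splits of 6 libraries into 3 and 3, no share under 0.1 can be had, so they do not decide on chance. The real split gave 0 genes, which any split must reach, so that all 10 splits gave as many carries no information. The highest other gave 5, with and without the 2-fold condition, for WT 1, WT 2 and slmyc2 3 against the rest. For gene lists the real split gave 7, and 2 splits gave as many, the highest other being 12 (WT 1, WT 2 and slmyc2 1 against the rest). Both of these highest splits keep WT 1 and WT 2 together, but the split with 5 genes gave 4 lists and the split with 12 lists gave 0 genes. Besides the real split, the remaining one that keeps them together, with slmyc2 2, gave 0 genes and 4 lists, and the split of WT 1, WT 3 and slmyc2 1 from the rest, which parts them, gave 1 gene and 3 lists. Without WT replicate 3 the real split gave 1755 genes, 1 of the 10 splits into 2 and 3 gave as many (the real one), and the highest other gave 2. Here too no share under 0.1 can be had. WT 1 and WT 2 stood apart from WT 3 as well as from the slmyc2 libraries. This count therefore cannot tell genotype from whatever else sets WT 1 and WT 2 apart.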
